A study of Homo sapiens with 14 samples.

How the data were processed

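RNA levels were measured in MCF7 cells, an established human breast adenocarcinoma line, on a one-colour Affymetrix expression array hybridized with biotin-labelled cRNA made from total RNA. The series holds 14 arrays in 7 groups of 2 replicates: untreated cells, and cells given 1 of 6 compounds for 6 h at 5 times the compound's own IC50, the concentration that inhibits by a fixed share in an assay the labels do not describe. The compounds were the HSP90 inhibitors 17AAG (tanespimycin), AUY922 and E973, the cyclin-dependent kinase (CDK) inhibitor CDK-887, and the topoisomerase inhibitors doxorubicin and SN38, the active metabolite of irinotecan. Absolute concentrations are not given, so compounds were compared at matched multiples of IC50 and matched time. The labels do not say whether the 2 replicates of a group were separate cultures. All p-values therefore measure only the spread between these samples, which may be technical.

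The deposited values are the authors' MAS5 signal intensity, 1 value for each of 54675 probe sets per array, on a linear scale (MAS5 per the submitters' processing notes, which give no version). In every array the mean signal after trimming 2% of the probe sets at each end was 500, which shows that the authors had scaled each array to this target; no other normalization between arrays was visible. Detection calls, the software version and a genome build are not given in the sources used here. Arrays have no read depth, and the number of arrays limits the precision. Over the arrays the median signal ran from 54.8 to 65.0 and the mean signal from 830.2 to 986.9.

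Signals below 1 were set to 1 and values were taken as log2. Of the probe sets, 41097 named 1 gene, 1801 named several genes and were left out, and 11777 had no gene name in the annotation used. Gene symbols were updated by gene ID from a RefSeq gene table (41043 probe sets matched, 54 kept as given). Each of the 19775 genes was represented by its probe set with the highest mean log2 signal over the 14 arrays. Genes were tested when that mean was at or above the 40th percentile of all probe sets (a signal of 26.8), which left 13962 genes. For 6979 of these genes more than 1 probe set passed the filter. HSPA1A and HSPA1B share their probe sets and were not measured separately. Values of other genes with near-identical relatives (RFPL2 and RFPL3, HSPA6, HSPA1L, MICB, RNA45SN5) are uncertain, because a probe set may also detect the relative.

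Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) over all 14 arrays in 1 fit, with 7 residual degrees of freedom and 14.1 in all per gene after moderation. A gene was called changed when its Benjamini-Hochberg adjusted p within the comparison was below 0.05 and its log2 fold change was at least 1 in size. All tests were two-sided. Each compound was compared with untreated cells, and compounds of a class were compared directly (E973 with 17AAG, E973 with AUY922, AUY922 with 17AAG, doxorubicin with SN38). Log2 fold changes are given with the standard error (SE) of the fit, with n = 2 arrays per group throughout. Every gene value named below is given as a log2 fold change unless it is called a signal.

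A set of 23 gene lists was written before the data were examined: heat shock response (HSF1) chaperones, unfolded protein response, integrated stress response (ATF4), proteasome subunits, p53 targets, replication-dependent histones, mitosis, G1/S and DNA replication (E2F), immediate-early and short-lived transcripts, estrogen receptor targets, transcripts of HSP90 clients, oxidative stress (NRF2), metallothioneins, cholesterol biosynthesis, NF-kappaB targets, CDKs with cyclins and transcription elongation, BCL2 family, DNA repair and Fanconi genes, ribosomal proteins, KRAB zinc finger factors, markers of cells other than breast epithelium, breast luminal epithelium, and drug targets. Members under the filter were not counted as measured. Each list was tested with limma's camera, which compares its genes with all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 23 lists and 6 compounds (138 tests), and again with an estimated correlation. Of these tests, 57 passed with the preset value and 17 of the 57 also passed with the estimated one. The direct comparisons formed a separate family of 4 comparisons and 23 lists. The calls of list members were repeated with p-values adjusted over the list alone. That count is printed where it differs from the count over all genes tested. Everywhere else both counts were equal.

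The genes named in the text were chosen by a rule fixed before the data were examined. Per compound, these are the 8 called genes with the largest rise and the 8 with the largest fall for which both treated arrays lay on the same side of both untreated arrays. Up to 3 called members with the largest absolute change were added for every list with at least 3 called members, together with the drug targets whatever their values. Per direct comparison the 3 highest and 3 lowest called genes were taken with the same condition of no overlap. The text gives those that fit its gene groups, and any gene outside the rule is said to be chosen after its values were seen. The similarity of compounds was measured as Pearson's correlation and covariance of log2 fold changes over the genes tested, set against 100 simulated groups without any change that share the 2 untreated arrays.

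Alternatives tried were quantile normalization, median centring, no filter, a filter at the 60th percentile (a signal of 103.3), a floor or an added constant at the 20th percentile (a signal of 9.34), the median of a gene's probe sets, only the 4 arrays compared, no mean-variance trend, a replicate block, adjusted p alone, adjustment over the whole family, an estimated inter-gene correlation, and leaving out each array. Scaling on 24 poly-A control probe sets, bacterial transcripts added to the RNA before labelling, was added after their signal was seen. The fit was tested on simulated data: 200 genes were changed in data with the spread of these arrays, and of 50 genes changed by 1 on the log2 scale 14 to 22 were called, of 50 changed by 2, 36 to 45, and of 50 changed by 3, 40 to 48, over the 10 comparisons. Between 2 and 7 unchanged genes were called per comparison. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.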

Results

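RNA was profiled in MCF7 cells, an estrogen receptor positive breast adenocarcinoma line, on 14 arrays in 7 groups of 2: untreated cells and cells exposed for 6 h to 17AAG, AUY922, E973, CDK-887, doxorubicin or SN38, each at 5 times its IC50. Over the 13962 genes tested, the 2 replicates of a group correlated with r from 0.962 (CDK-887) to 0.975 (AUY922). The between-replicate SD on the log2 scale was 0.528 for CDK-887 and 0.398 to 0.448 for the other groups. RNA quality was even across arrays: the signal ratio of 3' to 5' probe sets ran from 0.934 to 1.014 for GAPDH and from 1.118 to 1.231 for beta-actin. Scaling on the added poly-A controls moved the median of all genes from near 0 to -0.453 with 17AAG, -0.256 with AUY922, -0.285 with E973, -1.053 with CDK-887, -0.292 with doxorubicin and -0.648 with SN38, so all changes are relative to the bulk of transcripts. The main medians were 0.10 with SN38 and -0.087 with CDK-887.

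Which transcripts each compound changes within 6 h was the question of the comparisons with untreated cells. CDK-887 changed most genes, with 362 higher and 2716 lower, and AUY922 fewest, with 21 higher and 3 lower. SN38 raised 678 genes and lowered 1110, doxorubicin raised 254 and lowered 292, E973 raised 170 and lowered 116, and 17AAG raised 129 and lowered 96. For 3075 of the 3078 genes called with CDK-887 and every gene called with the other compounds, both treated arrays lay on the same side of both untreated arrays, which the call itself favours. Over all genes tested 46.1% (AUY922) to 75.6% (CDK-887) lay so, where chance gives 33.3% of unchanged genes. Where a called gene had another probe set above the filter, that probe set moved the opposite way by at least 1 for 108 of 1609 genes with CDK-887, 59 of 1063 with SN38, 4 of 249 with doxorubicin, 7 of 122 with E973, 4 of 92 with 17AAG and 0 of 14 with AUY922. Leaving out 1 array turned the balance of rises and falls for 17AAG (110 and 128 without 17AAG replicate 1, 107 and 143 without 17AAG replicate 2), for E973 (128 and 135 without E973 replicate 1) and for doxorubicin (268 and 260 without untreated replicate 1, 263 and 239 without untreated replicate 2). E973 lowered 71 genes without untreated replicate 2, doxorubicin raised 186 without doxorubicin replicate 2, and AUY922 lowered 0 or 1 without untreated replicate 1 or 2 and 6 without either of its own arrays.

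**Figure D1:**
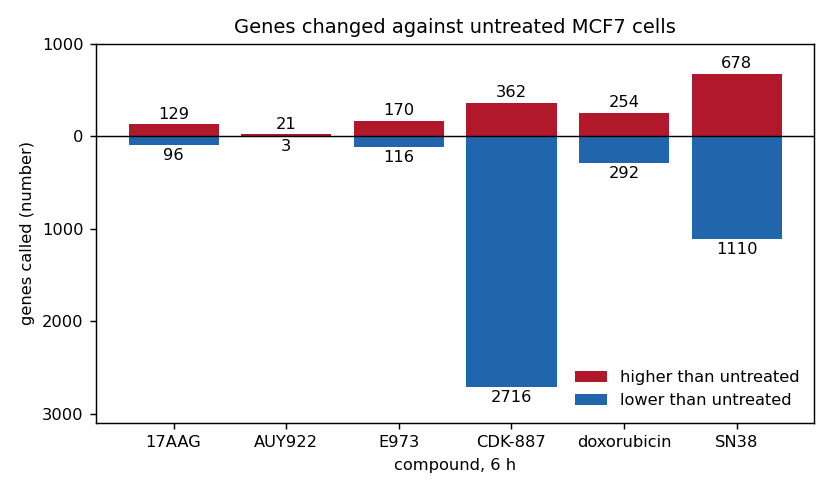
Number of genes called higher (above 0) or lower (below 0) than in untreated MCF7 cells after 6 h with each compound, of 13962 genes tested on 2 arrays per group. CDK-887 has 2716 lower and 362 higher, and AUY922 has 3 lower and 21 higher.

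17AAG raised the chaperones of the heat shock response and lowered growth-related, short-lived transcripts. HSPA6, an inducible HSP70 chaperone, rose by 6.08 ± 0.34 (SE, n = 2 and 2; adjusted p = 3.0e-08), from a mean signal of 52.6 to 3564.1. HSPA4L, an HSP110-type chaperone, rose by 2.84 ± 0.09 (adjusted p = 7.0e-11) and the HSP40 co-chaperone DNAJB4 by 2.68 ± 0.15 (adjusted p = 3.0e-08). ID1, an inhibitor of basic helix-loop-helix transcription factors, fell by 3.48 ± 0.12 (adjusted p = 1.3e-10), from a signal of 20088.4 to 1795.3. Its relative ID2 fell by 2.30 ± 0.08 and the growth regulator MYC fell by 2.18 ± 0.09 (adjusted p = 2.2e-10 and 1.6e-09).

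Of 26 measured heat shock members, 15 rose with 17AAG (16 adjusted over the list alone), none fell and 11 did not pass; the mean was 1.41 and the list rose as a whole (adjusted p = 3.6e-43, and 0.00228 with an estimated correlation). In the immediate-early list, 13 of 34 members fell and none rose (mean -0.82, adjusted p = 1.3e-15, and 0.00299 with an estimated correlation). The E2F list of G1/S and DNA replication genes was lower by a small shared amount, with 0 of 28 members called (mean -0.42, adjusted p = 3.3e-13, and 0.0179 with an estimated correlation). Some lists without any called member were higher relative to other genes: mitosis (mean 0.24, adjusted p = 1.6e-07, and 0.0463 with an estimated correlation), unfolded protein response (0.19, 2.3e-05 and 0.0179) and oxidative stress (0.30, 9.0e-06 and 0.033). Scaling on the poly-A controls turned these means to -0.18, -0.24 and -0.12. Among 25 estrogen receptor targets, CA12, a carbonic anhydrase, rose by 1.18 ± 0.09 while MYC and EGR3 (-1.16 ± 0.13) fell, and the list did not pass (mean -0.06, median 0.02, adjusted p = 0.828).

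Outside the lists, SH3BGR rose by 3.69 ± 0.21 (adjusted p = 4.6e-08) and PWWP3B by 3.33 ± 0.23 (adjusted p = 3.1e-07) with 17AAG. RFPL2 rose by 6.07 ± 1.16 from a signal of 12.5, below the filter, and its probe set may also read RFPL3. The largest falls besides ID1 were of dim transcripts: BMF, a pro-apoptotic BCL2 family gene, fell by 3.71 ± 1.01 to a signal of 8.3 (adjusted p = 0.0273). Other such falls were SPATA45 (-4.56 ± 0.87) and SSTR5-AS1 (-4.51 ± 0.57), to signals of 2.2 and 6.0. Of 22 named called genes, 8 (among them BMF and ZNF488) lost the call with 1 of the 4 arrays left out, 5 or 6 for each array (adjusted p 0.056 to 0.223). The poly-A controls were 1.343-fold higher than in untreated cells, and scaling on them gave 64 genes higher and 735 lower.

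E973 gave nearly the same picture as 17AAG. HSPA6 rose by 6.34 ± 0.34 (adjusted p = 1.7e-08) to a signal of 4255.2, HSPA4L by 2.90 ± 0.09 (adjusted p = 3.8e-11) and DNAJB4 by 2.90 ± 0.15 (adjusted p = 1.3e-08). ID1 fell by 3.88 ± 0.12 (adjusted p = 3.8e-11), ID2 fell by 2.41 ± 0.08 and EGR1, an immediate-early transcription factor, fell by 2.30 ± 0.17 (adjusted p = 5.0e-07). SH3BGR and PWWP3B rose by 3.84 ± 0.21 and 3.38 ± 0.23. The amino-acid stress genes CHAC1 (-1.32 ± 0.31), ATF3 (-1.19 ± 0.19; -0.52 and not called with the median of the gene's probe sets) and TRIB3 (-1.03 ± 0.09) fell.

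Of 26 heat shock members 15 rose with E973 (16 adjusted over the list alone) and none fell (mean 1.43, adjusted p = 7.4e-38, and 0.00256 with an estimated correlation). In the immediate-early list 14 of 34 members fell (mean -0.81, adjusted p = 6.2e-13, and 0.00481 with an estimated correlation). The E2F list was lower with 1 called member (mean -0.45, adjusted p = 8.7e-13, and 0.0179 with an estimated correlation). Mitosis genes were higher by a mean of 0.24 with 0 calls (adjusted p = 3.2e-07, and 0.0463 with an estimated correlation), a mean that scaling on the poly-A controls brought to 0.00. The ATF4 list as a whole did not pass (3 of 19 lower, mean -0.26, adjusted p = 0.137), nor did the estrogen receptor targets (CA12 rose by 1.07, MYC fell by 2.13 and EGR3 fell by 1.01; mean -0.09, adjusted p = 0.918). Of 26 named called genes 12, CHAC1, TRIB3 and EGR3 among them, lost the call with 1 of the 4 arrays left out, 7 to 12 for each array (adjusted p 1.0e-04 to 0.212, the lowest where the change slipped under the size threshold). The poly-A controls were 1.187-fold higher than in untreated cells, and scaling on them gave 99 genes higher and 297 lower.

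AUY922 at its matched multiple of IC50 raised heat shock genes by less than 17AAG and E973, and few other genes passed. HSPA6 rose by 3.29 ± 0.34 (adjusted p = 1.2e-04) to a signal of 515.7 and HSPA4L by 1.90 ± 0.09 (adjusted p = 1.8e-08). The HSP40 genes DNAJA4 and DNAJB4 rose by 1.82 ± 0.07 and 1.38 ± 0.15 (adjusted p = 9.2e-09 and 1.9e-04). MICB, a ligand of the natural killer cell receptor NKG2D, rose by 1.70 ± 0.16, and CSRP2 by 1.68 ± 0.10. ADCY7, an adenylate cyclase, rose by 2.00 ± 0.32 (adjusted p = 0.00637).

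Of 26 heat shock members 7 rose with AUY922 (8 adjusted over the list alone) and none fell (mean 0.80, adjusted p = 6.7e-42, and 0.00228 with an estimated correlation). No member of the immediate-early list was called (mean -0.13, adjusted p = 4.0e-04, but adjusted p = 0.062 with an estimated correlation). The E2F list had 0 calls in limma as well (mean -0.16, adjusted p = 8.3e-07, but adjusted p = 0.062 with an estimated correlation). The 3 genes that fell were LINC00851 (-3.60 ± 0.69, at a signal of 8.3), NFATC4 (-2.29 ± 0.36) and CFAP410 (-1.04 ± 0.19). With the median of the gene's probe sets NFATC4 and CFAP410 were at -0.11 and -0.14 and ADCY7 at 1.05, none of them called. Of 12 named called genes 6 lost the call with 1 of the 4 arrays left out, 3 to 6 for each array: FTCD, ADCY7, PWWP3B and these 3 (adjusted p 0.0594 to 0.229). At an unadjusted p under 0.05, 1760 genes differed where 698 are expected by chance. The count of 24 became 85 when p-values were adjusted over the whole family, and scaling on the poly-A controls, 1.176-fold higher here, gave 13 higher and 5 lower.

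How far HSP90 inhibitors act alike at matched multiples of IC50 was the question of the direct comparisons. All 3 raised the same 19 genes, among them HSPA6, HSPA4L, HSPH1, DNAJA4, DNAJB4, HSPB8, SERPINH1, CHORDC1, BAG2, SH3BGR and PWWP3B, and lowered none in common (names beyond the rule were chosen after their values were seen). 17AAG and E973 raised 119 genes in common and lowered 53, where independent lists would share 1.6 and 0.8. Of the 119 shared rises 19 were also called with AUY922, and of the 53 shared falls none.

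**Figure D2:**
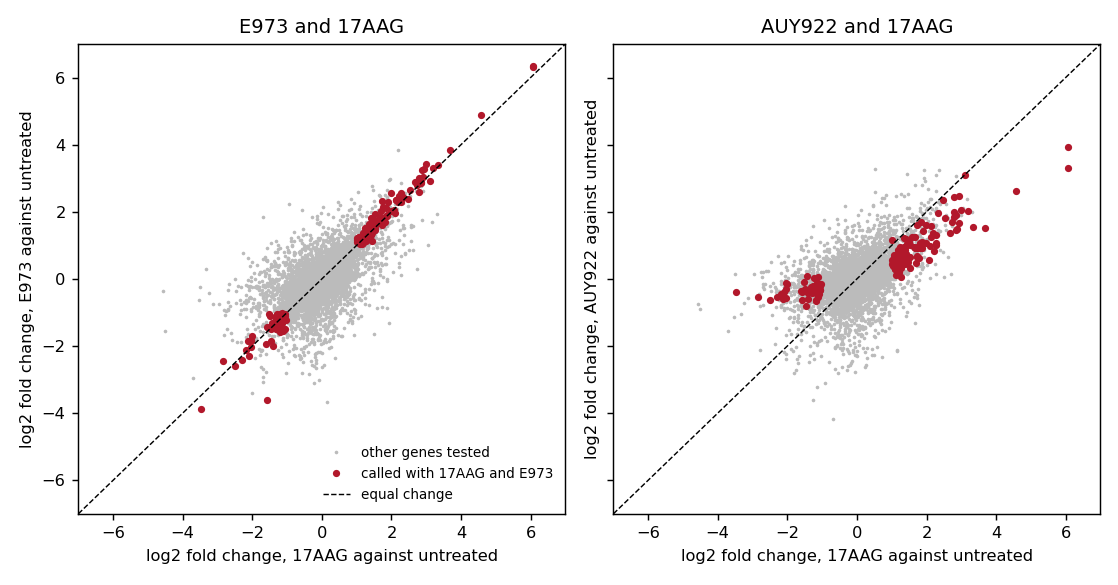
Log2 fold change against untreated cells of 13962 genes (grey) with 17AAG (horizontal) and with E973 (left) or AUY922 (right, vertical), red for the 172 genes called with 17AAG and E973, group means of 2 arrays. With E973 the red points lie along the line of equal change, and 19 of the 172 were also called with AUY922.

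Between E973 and 17AAG limma called 0 of 13962 genes. At an unadjusted p under 0.05, 837 genes differed where 698 are expected by chance, and 4 genes had an adjusted p under 0.05 alone. The heat shock lists differed by a mean of 0.02 (adjusted p = 0.789) and the immediate-early lists by 0.01 (adjusted p = 0.894), means of either sign under other scalings. Unfolded protein response genes were lower with E973 than with 17AAG by a mean of 0.26 (-0.09 on the poly-A scale) with 0 calls (adjusted p = 5.5e-20, and 0.00159 with an estimated correlation). The proteasome, ribosomal protein, luminal, ATF4 and drug target lists were lower with E973 by means of 0.09 to 0.13 in size, with 0 calls (adjusted p 3.0e-11 to 0.00951, but adjusted p 0.218 to 0.318 with an estimated correlation), and turned higher on the poly-A scale. That scale rests here on unlike E973 arrays: their poly-A controls lay at 7.677 and 7.309, against 7.659 and 7.684 with 17AAG. For 71.9% of the genes the 95% interval of the difference lay within 1 on the log2 scale, with a median width of 0.37 to each side, so smaller differences remain possible for single genes. Adjustment over the 4 direct comparisons together gave 30 genes, and leaving out 1 array gave 2 (without E973 replicate 2) to 4 (without 17AAG replicate 2).

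E973 and AUY922 differed in 77 genes, 31 higher and 46 lower with E973; the split was 19 and 57 or 21 and 64 without E973 replicate 1 or 2, and 37 and 36 or 39 and 34 without AUY922 replicate 1 or 2. HSPA6 was higher with E973 by 3.04 ± 0.34 (adjusted p = 1.0e-04), and ID1 was lower (-3.49 ± 0.12, adjusted p = 4.9e-10; signals of 1362.9 and 15330.6). In the heat shock list 3 of 26 members were higher with E973 (mean 0.63, adjusted p = 9.6e-31, and 0.00296 with an estimated correlation). In the immediate-early list 13 of 34 were lower (mean -0.67, adjusted p = 1.8e-16, and 0.00296 with an estimated correlation). AUY922 and 17AAG differed in 73 genes, 46 higher and 27 lower with AUY922, a split that became 35 and 32 with quantile normalization, 37 and 38 with median centring, and 120 and 13 with scaling on the poly-A controls. Without 17AAG replicate 1 or 2 it was 75 and 18 or 61 and 14, and without AUY922 replicate 1 or 2 it was 31 and 41 or 34 and 30. Here 2 heat shock members were lower with AUY922 (mean -0.60, adjusted p = 4.4e-30, and 0.00296 with an estimated correlation) and 13 immediate-early members were higher (mean 0.68, adjusted p = 6.0e-17, and 0.00296 with an estimated correlation).

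Unfolded protein response genes were lower with AUY922 than with 17AAG as well, with 0 calls (mean -0.26, -0.06 on the poly-A scale, adjusted p = 3.7e-10, and 0.00296 with an estimated correlation). Mitosis and E2F genes differed between AUY922 and each of the other HSP90 inhibitors by means of 0.25 to 0.30 in size, with 0 calls (adjusted p with an estimated correlation 0.0172 to 0.0311; mitosis genes, AUY922 against 17AAG, at -0.06 on the poly-A scale). NRF2 genes were higher with E973 than with AUY922 (mean 0.24, adjusted p = 1.7e-05, and 0.0301 with an estimated correlation) and lower with AUY922 than with 17AAG (mean -0.28, -0.09 on the poly-A scale, adjusted p = 1.0e-06, and 0.0191 with an estimated correlation), with 0 calls. The extremes of single genes in these comparisons were mostly dim, such as SPATA45 (3.81 ± 0.87, AUY922 minus 17AAG; signals of 31.1 and 2.2). Without 1 array 4 of the 6 named genes of E973 against AUY922 lost the call, all but HSPA6 and ID1 (adjusted p 0.0706 to 0.321). For AUY922 against 17AAG, 5 of 6 did, all but SSTR5-AS1 (adjusted p 0.0693 to 0.279). Each array left out removed 3 to 5 of these calls.

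Smaller list shifts in these comparisons had 0 called members, and their calls were lost with an estimated correlation. E973 against AUY922 gave means of 0.10 for proteasome, 0.25 for histone, 0.12 for cholesterol, 0.12 for ribosomal protein (-0.01 after quantile normalization) and -0.21 for metallothionein genes (adjusted p 5.3e-07 to 0.0443, but adjusted p 0.235 to 0.439 with an estimated correlation). AUY922 against 17AAG gave -0.19 for proteasome genes (0.00 on the poly-A scale), -0.30 for histone, -0.20 for cholesterol and -0.24 for ribosomal protein genes, 0.10 for DNA repair genes and -0.11 for drug targets (0.08 on the poly-A scale; adjusted p 6.0e-17 to 0.0497, but adjusted p 0.0765 to 0.317 with an estimated correlation). ATF4 targets did not differ as a list between E973 and AUY922 (1 lower, 2 adjusted over the list alone; mean -0.09, median 0.06, adjusted p = 0.464). The other lists did not pass (adjusted p 0.125 to 0.991 and 0.226 to 0.994).

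**Figure D3:**
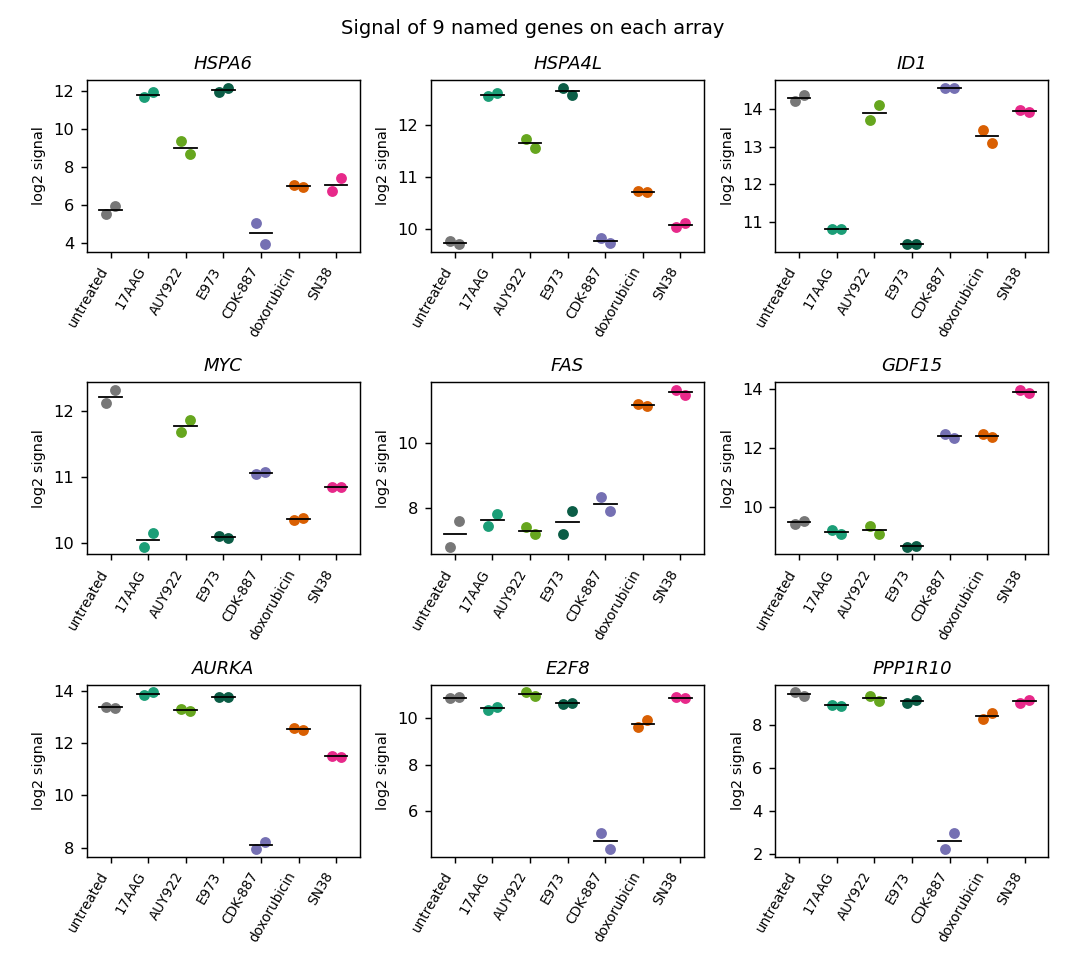
Log2 signal of 9 named genes on each of the 14 arrays, 2 points per group with a line at their mean; vertical axes differ between panels. HSPA6 reaches a mean signal of 3564.1 with 17AAG, 515.7 with AUY922 and 4255.2 with E973 against 52.6 in untreated cells, and AURKA is at 270.5 with CDK-887 against 10594.7.

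CDK-887 lowered 2716 genes, with mitotic kinases, replication genes, zinc finger factors and ATF4 targets among the largest falls. AURKA, a mitotic kinase, fell by 5.29 ± 0.08 (adjusted p = 6.1e-15), from a signal of 10594.7 to 270.5, and the spindle checkpoint kinase TTK fell by 5.06 ± 0.08 (adjusted p = 6.1e-15). E2F8, a repressor of the E2F family, fell by 6.15 ± 0.17 (adjusted p = 1.3e-12) and cyclin E2 (CCNE2) fell by 4.60 ± 0.09 (adjusted p = 4.0e-14). The E2F8 signals with CDK-887 were 33 and 21, around the filter signal of 26.8, so the exact size of its fall is uncertain. PPP1R10, a regulatory subunit of protein phosphatase 1, showed the largest computed fall (-6.81 ± 0.22, adjusted p = 6.1e-12), from a signal of 689.7 to 6.2. Its treated signal lay under the filter signal of 26.8, so the exact size and the rank of its fall are uncertain. Against these falls the p53 targets GDF15 and GADD45A rose by 2.91 ± 0.10 and 2.69 ± 0.10 (adjusted p = 1.0e-11 and 1.6e-11).

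Of 26 mitosis members 18 fell with CDK-887 and none rose (mean -1.84, adjusted p = 1.3e-09, and 0.0265 with an estimated correlation), the motor protein KIF11 (-4.10 ± 0.13) among them. In the E2F list 12 of 28 members fell, with CDT1, a replication licensing factor, at -3.51 ± 0.11; the mean was -1.17 and the median -0.26 (adjusted p = 0.00812, but adjusted p = 0.281 with an estimated correlation). Of 43 KRAB zinc finger factors 23 fell and 1 rose, with ZNF84 at -4.08 ± 0.10 and ZNF45 at -4.05 ± 0.16 (mean -1.13, adjusted p = 0.00177, but adjusted p = 0.149 with an estimated correlation). In the ATF4 list 8 of 19 fell and 1 rose (mean -1.29, adjusted p = 0.00616, but adjusted p = 0.281 with an estimated correlation). Its members CHAC1 (-5.45 ± 0.31), CEBPB (-3.68 ± 0.06) and DDIT3 (-3.64 ± 0.39) fell.

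Of 27 p53 targets 7 rose with CDK-887 and none fell, SESN1 by 1.86 ± 0.09 (mean 0.53, adjusted p = 0.00439, but adjusted p = 0.101 with an estimated correlation); the mean turned to -0.43 on the poly-A scale. With the median of the gene's probe sets SEL1L was at 0.40 and XBP1 at -0.93, neither of them called. By the brightest probe set the unfolded protein response list was mixed: HERPUD1 (-2.36 ± 0.09), SEL1L (-1.41 ± 0.08) and XBP1 (-1.22 ± 0.07) fell and 1 member rose. Its mean of 0.21 (adjusted p = 0.00439, but adjusted p = 0.0627 with an estimated correlation and 0.0639 after quantile normalization, where the alternatives gave 0.00126 to 0.487) became -0.75 on the poly-A scale. In the immediate-early list 12 of 34 fell and 4 rose without a shift of the list (mean -0.36, adjusted p = 0.545), among them SGK1 (-2.79 ± 0.11) and BTG1 (-2.42 ± 0.09). In the DNA repair list 11 of 29 fell, with FANCF at -3.63 ± 0.13 and MSH6 at -2.34 ± 0.09, and the list missed the threshold (mean -0.75, adjusted p = 0.054). It passed with quantile normalization (0.0403), no filter (0.00675), the poly-A scale (0.00418) and without untreated replicate 1 (0.0476), where the alternatives gave 0.00418 to 0.281.

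Among the kinases themselves, CDK7 fell by 2.79 ± 0.11 (adjusted p = 3.7e-11) and CDK9 by the brightest probe set fell by 1.39 ± 0.15 (adjusted p = 1.6e-06) with CDK-887. CDK1 (-0.29), CDK2 (0.19) and CDK4 (0.48) were under the size threshold and so not called. MEPCE, part of the complex that holds CDK9 inactive, fell by 3.28 ± 0.07. In the list of CDKs, cyclins and elongation factors 11 of 33 fell (mean -0.72, adjusted p = 0.137). Over all 13962 genes tested 2716 were lower. The lists named next had shares of called falls near or below that share, with 26 heat shock, 14 NRF2 and 14 cholesterol members measured. Members of lists that did not shift as a whole also fell: 3 heat shock genes (DNAJB1 at -2.13 ± 0.07; list mean -0.13, median 0.02, test direction up, adjusted p = 0.251), 3 NRF2 genes (SLC7A11 at -2.53 ± 0.14; mean -0.44, adjusted p = 0.984) and 3 cholesterol genes (IDI1 at -1.28 ± 0.09; mean -0.16, median 0.01, test direction up, adjusted p = 0.828). In the BCL2 family 3 of 17 fell (BOK at -2.14 ± 0.16) and 1 rose (mean -0.32, adjusted p = 0.918), and 4 of 25 estrogen receptor targets fell (MYB at -3.22 ± 0.14; mean -0.10, median 0.18, test direction up, adjusted p = 0.298).

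The largest rises with CDK-887 started from dim signals: ALDH8A1 rose by 5.59 ± 0.70 from 20.5 to 990.2, and FBXL13 and HUS1B by 5.46 ± 1.30 and 5.30 ± 0.87 from 5.9 and 10.3. The poly-A controls were 1.954-fold higher in this group than in untreated cells, the largest difference of any group. The split of 362 higher and 2716 lower became 742 and 2204 with quantile normalization and 41 and 6639 with scaling on these controls. With the median over a gene's probe sets SEL1L and CDK9 turned to 0.40 and 0.29, and GDF15 (1.75), MSH6 (-1.17), XBP1 (-0.93), BOK (-0.99) and IDI1 (-0.38) lost their calls. HSPA6 (-1.23), HSPA1L (-2.06) and SND1-IT1 (3.93) lost their calls without CDK-887 replicate 2 (adjusted p 0.052 to 0.196); without untreated replicate 1 or 2 at most 2 of the 56 named calls were lost.

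Doxorubicin, an anthracycline that poisons topoisomerase II, raised p53 targets above all. FAS, a death receptor, rose by 4.0 ± 0.26 (adjusted p = 1.2e-07), from a signal of 145.0 to 2317.4. GADD45A, a stress-induced growth arrest gene, rose by 3.10 ± 0.10 (adjusted p = 7.2e-11) and the kinase PLK3 by 3.95 ± 0.88 (adjusted p = 0.00431). FOSL1, an AP-1 subunit, rose by 4.07 ± 0.39 (adjusted p = 5.1e-06). MYC fell by 1.85 ± 0.09 (adjusted p = 1.2e-08), and INHBE, an activin subunit gene, fell by 4.35 ± 0.60 (adjusted p = 1.3e-04).

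Of 27 p53 targets 22 rose with doxorubicin and none fell (mean 2.00, adjusted p = 1.6e-36, and 9.6e-04 with an estimated correlation). In the mitosis list 4 of 26 fell, PLK1 (-1.62 ± 0.14) and BUB1B (-1.23 ± 0.13) among them, while CDC20, the activator of the anaphase-promoting complex, rose by 1.27 ± 0.15 (mean -0.57, adjusted p = 1.4e-11, and 0.0179 with an estimated correlation). The other lists that passed lost the call with an estimated correlation. In the ATF4 list 4 of 19 fell (CHAC1 at -1.96 ± 0.31) and 2 rose (mean -0.39, adjusted p = 0.00779, but adjusted p = 0.284 with an estimated correlation and 0.0664 without untreated replicate 2, where 1 array left out gave 6.1e-04 to 0.0664). In the E2F list 3 of 28 fell, with CDT1 at -1.17 ± 0.11 (mean -0.22, adjusted p = 0.0138, but adjusted p = 0.285 with an estimated correlation and 0.0645 without doxorubicin replicate 2, where 1 array left out gave 0.00599 to 0.0645). Of 43 KRAB zinc finger factors 4 fell (ZNF184 at -1.76 ± 0.16) and 3 rose (ZNF37A at 1.90 ± 0.26), with a mean of -0.27 (adjusted p = 0.00276, but adjusted p = 0.166 with an estimated correlation).

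In the DNA repair list 1 of 29 fell with doxorubicin (mean -0.34, adjusted p = 4.2e-04, but adjusted p = 0.0718 with an estimated correlation). The immediate-early list split, with 5 of 34 lower and 2 higher, FOS by 1.72 ± 0.16 (mean -0.16, adjusted p = 0.104), and so did the CDK and cyclin list, with WEE1 lower (-1.43 ± 0.27), ELL2 and POLR2A higher (1.21 ± 0.12 and 1.16 ± 0.27) and no shift (mean -0.04, adjusted p = 0.669). TOP1, whose enzyme is the target of SN38, was higher by 0.58 ± 0.06 (adjusted p = 1.2e-05), under the size threshold. TOP2A (-0.29) and TOP2B (-0.04) were under this threshold as well and not called. With the median of the gene's probe sets PLK3 (1.94), ELL2 (0.96) and POLR2A (0.70) were not called. Of 35 named called genes 6 lost the call with 1 array left out, 3 or 4 for each array: CDIP1, POU2F3, E2F8, ORC1, POLR2A and ZNF264 (adjusted p 0.00545 to 0.199). The poly-A controls were 1.227-fold higher than in untreated cells, and scaling on them gave 126 genes higher and 840 lower.

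SN38, a topoisomerase I poison, raised p53 targets and lowered mitotic genes and estrogen receptor targets. GADD45A rose by 4.49 ± 0.10 and the stress cytokine GDF15 by 4.40 ± 0.10 (both adjusted p = 1.5e-12), GDF15 from a signal of 719.3 to 15190.1. FAS rose by 4.38 ± 0.26 (adjusted p = 7.3e-09), NHLH2 by 5.53 ± 0.42 (adjusted p = 7.3e-08) and FOSL1 by 5.07 ± 0.39 (adjusted p = 9.9e-08). The pro-apoptotic genes PMAIP1 and BAX rose by 2.44 ± 0.08 and 1.82 ± 0.19, and BCL2 by the brightest probe set fell by 1.36 ± 0.24 (-0.11 and not called with the median of the gene's probe sets). The progesterone receptor gene PGR, an estrogen receptor target, fell by 2.06 ± 0.11 (adjusted p = 3.3e-09).

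Of 27 p53 targets 25 rose with SN38 and none fell (mean 2.35, adjusted p = 1.4e-23, and 0.00211 with an estimated correlation). In the mitosis list 15 of 26 fell, BUB1B (-3.0 ± 0.13) and CENPE (-2.63 ± 0.16) among them, and CDC20 rose by 2.20 ± 0.15 (mean -1.03, adjusted p = 2.1e-11, and 0.0179 with an estimated correlation). Of 25 estrogen receptor targets 6 fell, with SLC7A2 at -1.92 ± 0.09 and NRIP1 at -1.54 ± 0.13 (mean -0.48, adjusted p = 0.0018, and 0.0463 with an estimated correlation). In the DNA repair list 7 of 29 fell, with XRCC4 at -2.17 ± 0.16, RAD50 at -1.70 ± 0.11 (-0.21 and not called with the median of the gene's probe sets) and BARD1 at -1.70 ± 0.11 (mean -0.46, adjusted p = 0.00219, but adjusted p = 0.101 with an estimated correlation). In the immediate-early list 4 of 34 rose, IER5 by 2.01 ± 0.07, and MYC fell by 1.37 ± 0.09 (mean 0.40, -0.35 on the poly-A scale; adjusted p = 0.00286, but adjusted p = 0.096 with an estimated correlation).

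The ATF4 list split with SN38, 5 of 19 lower (SLC7A11 at -2.87 ± 0.14) and 2 higher (ATF3 at 2.53 ± 0.19), with a mean of -0.40 (adjusted p = 0.0126, but adjusted p = 0.29 with an estimated correlation). Of 43 KRAB zinc finger factors 3 rose, ZNF37A by 1.98 ± 0.26 (mean 0.38, -0.37 on the poly-A scale; adjusted p = 0.00621, but adjusted p = 0.211 with an estimated correlation). Transcripts of HSP90 clients were lower (2 of 15 called, mean -0.51, adjusted p = 0.0387, but adjusted p = 0.153 with an estimated correlation); both called members, ESR1 (-2.61) and CDK6 (-1.42), encode the estrogen receptor and a CDK, ESR1 being chosen after its value was seen. In the heat shock list 3 of 26 rose, HSPA6 by 1.34 ± 0.34, and 1 fell (mean 0.18, -0.01 after median centring and -0.57 on the poly-A scale, adjusted p = 0.221). CDK12 (-1.55 ± 0.12) and CDK6 (-1.42 ± 0.15) fell while POLR2A rose by 1.25 ± 0.27, without a shift of the CDK and cyclin list (3 of 33 higher, 4 lower, mean -0.02, adjusted p = 0.918).

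TOP2A fell by 1.03 ± 0.12 with SN38 (adjusted p = 4.2e-06). TOP1, whose enzyme is the target of SN38, was at -0.30 ± 0.06, under the size threshold, and so was not called. Among the largest falls were MAML3 (-3.61 ± 0.26, adjusted p = 4.6e-08) and MIPOL1 (-4.19 ± 0.62, to a signal of 19.2). The poly-A controls were 1.679-fold higher than in untreated cells. The split of 678 higher and 1110 lower became 429 and 1558 with median centring and 152 and 3811 with scaling on these controls. With the median of the gene's probe sets CDK6 (-0.85), POLR2A (0.70) and HSPA6 (0.95) were not called. CRYAB, HSPA6 and TOP2A lost their calls with 1 array left out, 2 of them without SN38 replicate 2 and 1 without untreated replicate 1 (adjusted p 1.5e-04 to 0.0688, the lowest where the change slipped under the size threshold).

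Doxorubicin and SN38 raised 189 genes in common and lowered 90, where independent lists would share 12.3 and 23.2, and 1 gene went opposite ways. Compared directly, 1185 genes differed, 684 higher and 501 lower with doxorubicin; median centring gave 1065 and 291, and scaling on the poly-A controls 1902 and 144. KRAB zinc finger factors were lower with doxorubicin, 9 of 43 called (10 adjusted over the list alone; mean -0.65, adjusted p = 8.3e-09, and 0.0209 with an estimated correlation). Immediate-early members were lower too, 7 of 34 called (mean -0.56, adjusted p = 1.4e-07, and 0.0172 with an estimated correlation). Mitosis members were higher with doxorubicin, 6 of 26 called (mean 0.46, adjusted p = 6.0e-05, but adjusted p = 0.0936 with an estimated correlation). Of 27 p53 targets 5 were lower with doxorubicin (mean -0.35, 0.10 on the poly-A scale; adjusted p = 0.00166, but adjusted p = 0.0854 with an estimated correlation). Of 25 estrogen receptor targets 4 were higher (mean 0.30, adjusted p = 0.0226, but adjusted p = 0.103 with an estimated correlation, 0.0741 with the 60th percentile filter and 0.122 with the median of the gene's probe sets, where the alternatives gave 0.00192 to 0.122). Histone genes were lower with doxorubicin, 1 of 14 called (mean -0.57, adjusted p = 3.9e-04, but adjusted p = 0.218 with an estimated correlation), and so were ribosomal protein genes, with 0 calls (mean -0.14, 0.05 after median centring and 0.32 on the poly-A scale; adjusted p = 0.00531, but adjusted p = 0.667 with an estimated correlation). GJB5, a connexin gene, was lower with doxorubicin by the largest computed amount (-5.40 ± 0.92, adjusted p = 3.1e-04; signals of 7.1 and 298.3), and PDCD4 was lower as well (-3.59 ± 0.84). The doxorubicin signal of GJB5 lay under the filter signal of 26.8, so the exact size and the rank of its difference are uncertain.

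**Figure D4:**
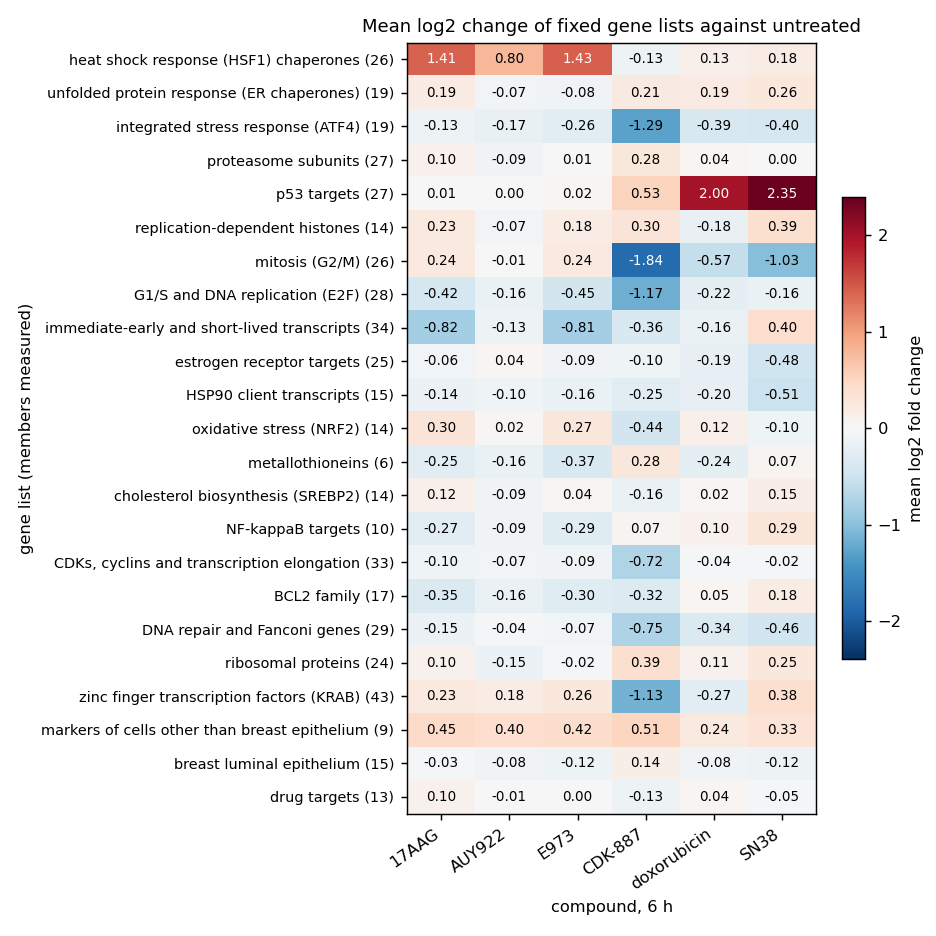
Mean log2 fold change against untreated cells of the measured members of each of the 23 gene lists (members measured in brackets) with each compound, 2 arrays per group. Heat shock genes are at 1.41, 0.80 and 1.43 with the HSP90 inhibitors, p53 targets at 2.00 and 2.35 with doxorubicin and SN38, and mitosis genes at -1.84 with CDK-887; on the poly-A scale means near 0 such as that of p53 targets with CDK-887 (0.53) turn negative.

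Other lists shifted by small amounts, and these calls were lost with an estimated correlation. Ribosomal protein genes had 0 called members. Their means, with the value after quantile normalization in brackets, were 0.10 with 17AAG (-0.01), -0.15 with AUY922 (-0.02), 0.39 with CDK-887 (0.04), 0.11 with doxorubicin (0.01) and 0.25 with SN38 (0.03). The calls (adjusted p 6.3e-10 to 0.00384) were lost with quantile normalization (adjusted p 0.194 to 0.804) and with an estimated correlation (adjusted p 0.292 to 0.589). Each positive mean turned negative on the poly-A scale. Proteasome genes had 0 called members and means of 0.10 with 17AAG, -0.09 with AUY922 and 0.28 with CDK-887 (-0.07 after quantile normalization; adjusted p 5.5e-06 to 4.3e-04, but adjusted p 0.281 to 0.338 with an estimated correlation), the positive ones negative on the poly-A scale. KRAB zinc finger factors were higher with 17AAG (1 called, mean 0.23), AUY922 (0 called, 0.18) and E973 (1 called, 0.26; adjusted p 6.0e-05 to 4.2e-04, but adjusted p 0.0759 to 0.102 with an estimated correlation), and the first and second of these means turned to -0.20 and -0.05 on the poly-A scale. Histone genes had 0 called members, with means of 0.23 with 17AAG, 0.30 with CDK-887 and 0.39 with SN38 (adjusted p 0.00657 to 0.0337, but adjusted p 0.29 to 0.354 with an estimated correlation), all negative on the poly-A scale.

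Unfolded protein response genes had means of 0.19 with doxorubicin (0 called, adjusted p = 0.00181, but adjusted p = 0.0506 with an estimated correlation) and 0.26 with SN38 (1 called, adjusted p = 0.012, but adjusted p = 0.0896 with an estimated correlation), both negative on the poly-A scale. NRF2 genes had means of 0.27 with E973 (0 called, adjusted p = 4.0e-04, but adjusted p = 0.062 with an estimated correlation) and 0.12 with doxorubicin (1 lower, -0.18 on the poly-A scale; adjusted p = 0.0472, but adjusted p = 0.268 with an estimated correlation). Heat shock genes with doxorubicin (1 called, mean 0.13, -0.17 on the poly-A scale), ATF4 targets with AUY922 (0 called, -0.17) and DNA repair genes with 17AAG (0 called, -0.15) passed at 0.039, 0.039 and 0.0151, but with an estimated correlation the adjusted p values were 0.354, 0.347 and 0.198. Metallothioneins with E973 had 0 called members and a mean of -0.37 (adjusted p = 0.0137, but adjusted p = 0.281 with an estimated correlation). Luminal epithelium genes had a mean of -0.08 with AUY922 (0 called, adjusted p = 0.0475) and 0.14 with CDK-887 (2 lower, adjusted p = 0.0158, -0.14 after quantile normalization and -0.83 on the poly-A scale), with adjusted p = 0.347 and 0.29 with an estimated correlation.

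The remaining tests of the 23 lists against untreated cells did not pass. With the HSP90 inhibitors the p53 targets had 0 called members in limma and means of 0.01, 0.00 and 0.02 (adjusted p = 0.664, 0.733 and 0.792), and HSP90 client transcripts had 1 called member, with E973 (adjusted p 0.137 to 0.171). Adjusted p ran from 0.0857 to 0.934 over the 12 such lists with 17AAG, 0.0769 to 0.911 over 15 with AUY922, 0.085 to 0.918 over 16 with E973, 0.054 to 0.984 over 13 with CDK-887, 0.104 to 0.912 over 13 with doxorubicin and 0.109 to 0.918 over 12 with SN38. The BCL2 family list had 1 member lower with E973, and 2 adjusted over the list alone. Markers of cells other than breast epithelium had 9 measured members, of which 1, COL1A1 (1.53 with 17AAG and 1.94 with E973, chosen after its values were seen), was called. Of the HSP90 genes, HSP90AB1 was higher by 0.52 with 17AAG, 0.22 with AUY922 and 0.49 with E973, and HSP90AA1 by 0.26, -0.02 and 0.12. All of these were under the size threshold, so none was called.

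Profiles of fold changes over 13962 genes, which are not independent replicates, were correlated for all 15 pairs of compounds, all of which share the 2 untreated arrays. Unchanged groups that share these arrays gave a simulated r of 0.500 and a covariance of 0.086. The covariance was 0.210 for 17AAG and E973 (r = 0.688), 0.132 for 17AAG and AUY922 (r = 0.528), 0.140 for AUY922 and E973 (r = 0.552) and 0.288 for doxorubicin and SN38 (r = 0.552). CDK-887 reached 0.279 with doxorubicin (r = 0.403) and 0.292 with SN38 (r = 0.315). The excess over the simulated covariance was 0.124, 0.046, 0.054 and 0.201 for the pairs within a class and 0.193 and 0.206 for CDK-887 with the topoisomerase inhibitors. For the other 9 pairs, which share the same untreated arrays, it was -0.006 to 0.016. Covariance grows with the size of the responses, so it does not rank pairs by likeness. CDK-887 and SN38 shared 131 called rises and 400 falls, and 112 called genes went opposite ways. For CDK-887 and doxorubicin these counts were 65, 204 and 47, and for doxorubicin and SN38 189, 90 and 1. Independent lists would share 17.6 rises and 215.9 falls for CDK-887 and SN38, and 6.6 and 56.8 for CDK-887 and doxorubicin. Other pairs across classes could also exceed such counts, as E973 and doxorubicin with 22 rises (3.1 expected) and 16 falls (2.4 expected). AUY922 and CDK-887 shared only 1 rise (0.5 expected) and 0 falls (0.6 expected). Simulated unchanged groups shared 0.00 called genes. This count is small by construction, because few genes are called where none is changed, so it does not gauge the overlaps seen here. The 2 controls could not be split into parts of 2 arrays, so part of r and of the overlap counts may come from shared controls.

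**Figure D5:**
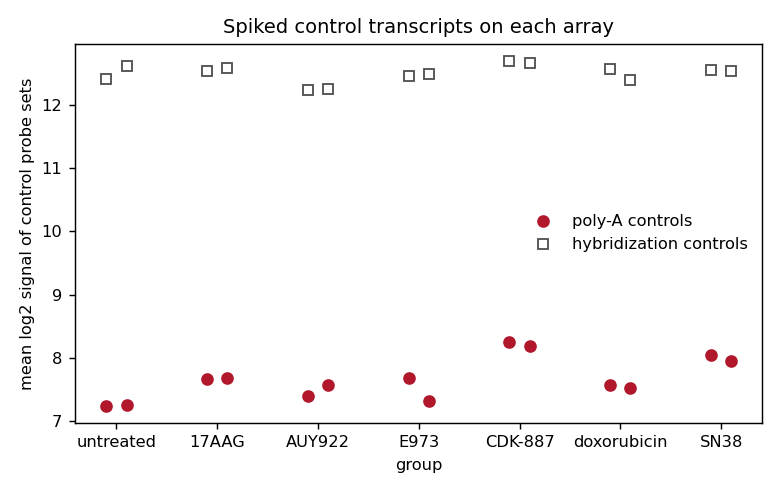
Mean log2 signal of 24 poly-A control probe sets (circles) and 18 hybridization control probe sets (squares) on each of the 14 arrays by group. The poly-A controls lie at 7.239 and 7.253 in untreated cells and at 8.180 and 8.244 with CDK-887.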

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

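Of the tests below, those of RNA degradation, messenger RNA content, the noise of the AUY922 arrays and a common factor were chosen after the result was seen, as was the scaling on the poly-A controls. The poly-A controls, bacterial transcripts used above for an alternative scaling alone, had a higher signal in all 6 treated groups than in untreated cells. The mean log2 difference was 0.966 with CDK-887, 0.747 with SN38, 0.426 with 17AAG, 0.295 with doxorubicin, 0.248 with E973 and 0.234 with AUY922. The lower array of each group (8.180, 7.940, 7.659, 7.525, 7.309 and 7.398 in this order) lay above the higher untreated array (7.253). The hybridization controls, which are added after labelling, differed by 0.168 with CDK-887, 0.043 with SN38, 0.050 with 17AAG, -0.027 with doxorubicin, -0.035 with E973 and -0.265 with AUY922. Relative to these controls the poly-A signal of E973 replicate 2 (-5.181) lay below that of untreated replicate 1 (-5.175). Every other treated array lay above both untreated arrays. On this measure the mean difference was 0.499 with AUY922, 0.376 with 17AAG and 0.282 with E973.

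With CDK-887 more genes fell (2716) than rose (362). The authors' scaling as the whole cause would need a share of falls under 60% once the scaling is replaced, and the share was 74.8% with quantile normalization and 86.5% with median centring. With 1 array left out these shares ran from 73.5% to 88.5%. A bound of 75% had been set beforehand for excluding this cause and 74.8% narrowly missed it, so the case against scaling rests on the distance from 60%, and scaling may account for part of the excess of falls. Degraded RNA would raise the ratio of 3' to 5' probe sets, but the higher CDK-887 array (log2 mean of 0.059) lay below the highest of the other 12 arrays (0.141).

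A lower messenger RNA content after CDK-887 could also raise the poly-A controls, since total RNA is matched and a fixed amount of control is added. The poly-A controls, taken relative to the hybridization controls, were 0.798 higher than in untreated cells, against a within-pair range of 0.189. This cannot be told apart from a larger amount of control added to these 2 samples, because the amounts are not given and go with the groups. On the poly-A scale 41 genes were higher and 6639 lower, so the number of transcripts that fell with CDK-887 stays open.

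AUY922 changed fewer genes (24) than 17AAG (225) and E973 (286). Noisier AUY922 arrays could lower this count alone in a fit with their own spread, not in the pooled one; with only the 4 arrays compared the counts were 25, 242 and 295, and the between-replicate SD was 0.398 for AUY922 and 0.419 or more for 17AAG and E973. A single factor on every response, as from a uniformly weaker effect, would give the same ratio for each gene group. Heat shock genes changed by 0.56 (0.52 to 0.61, members resampled) of the mean of 17AAG and E973 and immediate-early genes by 0.16 (0.07 to 0.24), a difference of 0.40 (0.31 to 0.50). These intervals cover the choice of list members alone, taken as independent. They leave out the spread between arrays, so they are too narrow to exclude a single factor by themselves. Over the 172 genes called with both 17AAG and E973 the slope was 0.49 and 169 had the same sign with AUY922, as a weaker shared response would give, though this selection and the shared untreated arrays favour both values. Unequal dose relations of ID1, MYC and the heat shock genes at the concentrations used may explain this, and were not tested, because each compound has 1 dose and 1 time.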

How the results depend on the processing

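Scaling on the poly-A controls and its results below were chosen after the data were seen, and so were the tests of the direct lists under each setting. Of 130 gene counts under other settings 112 stayed within 1.5 times the reported count, of 1001 list results 895 kept direction and side of the threshold, 70 lost the call, 8 gained one and 28 turned, and of 2247 results of called named genes 2126 were the same. With 1 array left out, which leaves a lone array that is assumed to vary like the other groups, 36 of 40 counts, 343 of 364 list results and 728 of 856 gene results were the same. Named genes called in every setting that tested them and with every array left out numbered 130 of 214. A setting in which a gene was not tested did not count against it. Counts on the poly-A scale were 799 with 17AAG, 6680 with CDK-887, 966 with doxorubicin, 3963 with SN38, 133 between AUY922 and 17AAG and 2046 between doxorubicin and SN38; this scale lowers all treated groups by construction. By adjusted p alone, without a size threshold, counts were 1718 (17AAG), 117 (AUY922), 2077 (E973), 7716 (CDK-887), 3597 (doxorubicin), 6130 (SN38), 4 (E973 against 17AAG), 676 (E973 against AUY922), 859 (AUY922 against 17AAG) and 4931 (doxorubicin against SN38). Adjustment over the whole family gave 85 with AUY922 and 30 for E973 against 17AAG, since families with strong responses raise the p threshold, and adjustment within the comparison, which gave 0 for E973 against 17AAG, gave 2 to 4 with 1 array left out. On the poly-A scale list means turned with 17AAG to -0.24 (unfolded protein response), -0.33 (proteasome), -0.19 (histones), -0.18 (mitosis), -0.12 (NRF2), -0.33 (ribosomal) and -0.20 (KRAB), with AUY922 to -0.05 (KRAB) and with E973 to 0.00 (mitosis). They turned with CDK-887 to -0.75 (unfolded protein response), -0.69 (proteasome), -0.43 (p53), -0.66 (histones), -0.57 (ribosomal) and -0.83 (luminal), and with doxorubicin to -0.17 (heat shock), -0.10 (unfolded protein response), -0.18 (NRF2) and -0.18 (ribosomal). They turned with SN38 to -0.48 (unfolded protein response), -0.36 (histones), -0.35 (immediate-early), -0.50 (ribosomal) and -0.37 (KRAB), and between doxorubicin and SN38 to 0.10 (p53). Quantile normalization turned the means to -0.01 (ribosomal, 17AAG), -0.07 (proteasome, CDK-887) and -0.14 (luminal, CDK-887) and weakened the unfolded protein response with CDK-887 to 0.10; the cause was not tested. With an estimated inter-gene correlation, which leaves the means, calls were lost for CDK-887 (unfolded protein response 0.21, ATF4 -1.29, p53 0.53, E2F -1.17, KRAB -1.13), doxorubicin (ATF4 -0.39, E2F -0.22, KRAB -0.27), SN38 (ATF4 -0.40, immediate-early 0.40, DNA repair -0.46, KRAB 0.38) and doxorubicin against SN38 (p53 -0.35, mitosis 0.46, estrogen receptor 0.30). The estimate lay below the preset 0.01 for the unfolded protein response (0.000) and estrogen receptor (-0.013) lists, so a larger correlation does not account for their losses. For the unfolded protein response list, E973 against 17AAG, the unadjusted camera p rose from 1.8e-21 to 1.7e-05 at this estimate. A call lost in the test with an estimated correlation is therefore not by itself evidence that the members of a list move together. The estrogen receptor call was lost also with the 60th percentile filter (0.30, fewer genes tested) and the median of the gene's probe sets (0.23, the cause was not tested). With arrays left out the doxorubicin means were -0.50 to -0.28 for ATF4 and -0.24 to -0.19 for E2F, each lost once. Calls of smaller lists were also lost without 1 array: histones and ribosomal genes with 17AAG, ATF4 and luminal genes with AUY922, heat shock, NRF2 and ribosomal genes with doxorubicin, and HSP90 clients with SN38 (adjusted p 0.0511 to 0.758). Calls were gained by ATF4 with E973 (poly-A scale, and without untreated replicate 1), the CDK and cyclin list with CDK-887 (no filter, poly-A scale), DNA repair with CDK-887 (quantile normalization, no filter, poly-A scale, and without untreated replicate 1) and immediate-early genes with doxorubicin (the median of the gene's probe sets, poly-A scale; adjusted p 0.00167 to 0.0476). With the median of the gene's probe sets SEL1L and CDK9 turned to 0.40 and 0.29 with CDK-887, because other probe sets differ, and 30 named calls were lost. Correlations without the filter were 0.506 (17AAG and AUY922), 0.561 (17AAG and E973), 0.523 (AUY922 and E973) and 0.518 (doxorubicin and SN38), and with the 60th percentile filter 0.606, 0.869, 0.680 and 0.572 in this order, for which the cause was not tested; AUY922 and CDK-887 turned to -0.003. With a floor 17AAG and E973 reached 0.709 and doxorubicin and SN38 0.559, with an added constant 0.741 and 0.564, with AUY922 and E973 at 0.570, and 0.565 with the median of the gene's probe sets. With 1 array left out the 4 ranges were 0.445 to 0.663, 0.589 to 0.766, 0.468 to 0.678 and 0.494 to 0.616. Differences between replicates 1 and 2 correlated by -0.029 to 0.050 over 21 pairs of groups, so the numbers do not pair the samples. With a replicate block counts were 222 (17AAG), 23 (AUY922), 283 (E973), 3071 (CDK-887), 545 (doxorubicin), 1782 (SN38), 0 (E973 against 17AAG), 75 (E973 against AUY922), 69 (AUY922 against 17AAG) and 1191 (doxorubicin against SN38), 90 of 91 list results and 209 of 214 gene calls were the same, and the luminal list with AUY922 lost its call (adjusted p = 0.0598, alternatives 0.00117 to 0.768). In all, 144 of 214 named calls held in every other setting in which the gene was tested. Settings for dim signals lost few calls: 4 with a floor, 6 with an added constant and 5 with no filter. More were lost with the median of the gene's probe sets (30), only the 4 arrays compared (28) and the poly-A scale (21). Dim genes remain less certain, as 82 of the 214 were not tested with the 60th percentile filter. With the median of the gene's probe sets 190 of the 214 were tested, and with a floor 213.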

Other observations

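Of the tests below, the 3 on very large genes were chosen before their results were seen, though after the largest falls with SN38, which the list leaves out; the lists of BMP and TGF-beta targets and of death receptors, and the choice of RNA45SN5, came after the result was seen. Transcripts of very large genes fell with SN38. A hand-written list of 62 such genes had 47 measured members, of which 25 were lower with SN38 and none higher, ATXN1 by -3.22, EXOC6B by -2.99 and PARD3 by -2.66 (genes chosen after their values were seen). Their mean was -1.24 (-1.53 to -0.94, members resampled; p = 5.6e-04 with an estimated correlation), in line with an effect of transcription unit length. Dim signals would give such a mean to other genes as well, but 100% of 10000 random lists matched on mean signal had a higher mean (-0.46 to 0.41). A fall of equal size with both compounds would leave no difference, but SN38 lowered the members by 0.92 more than doxorubicin (difference -0.92, -1.17 to -0.65), 43 of 47 in this direction. The intervals from resampled members leave out the spread between arrays. A shared fall that is weaker with doxorubicin is not excluded, because compounds may differ in strength. With doxorubicin 2 members were lower (mean -0.32, p = 0.0234 with an estimated correlation), and with CDK-887 7 were higher and 5 lower (mean 0.20, upward, p = 0.0288 with an estimated correlation, but -0.76 on the poly-A scale). Stalled elongation in long genes after topoisomerase I poisoning is a candidate explanation that none of these tests addresses. Genomic lengths were not at hand, so the list rests on known large genes.

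Some BMP and TGF-beta targets fell with 17AAG and E973. The list was prompted by the falls of ID1 and ID2 and holds them, so a p-value of the whole list is no evidence and is left out. Of 13 measured members limma called 6 lower with 17AAG (mean -1.30) and 7 with E973 (mean -1.25). The inhibitory SMAD genes SMAD6 (-2.04 and -1.83) and SMAD7 (-1.40 and -1.99) and PMEPA1 (-2.02 and -1.71) fell besides ID1, ID2 and ID3, which the immediate-early list also holds. No member was called with AUY922 (mean -0.17), and 5 were higher with AUY922 than with 17AAG (mean 1.13).

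In a list of death receptors, ligands and related genes, 4 of 8 measured members rose with doxorubicin (mean 1.63) and 4 with SN38 (mean 1.72). The list was prompted by FAS and holds it, so a p-value is left out for the same reason. Besides FAS the members that rose were TNFRSF10A (3.02 and 2.71), TNFRSF10B (2.83 and 2.11) and the decoy receptor TNFRSF10C (4.81 and 4.79, each ± 0.88). FAS and TNFRSF10B also belong to the p53 list. The other members were not called: TNFSF10 was higher (0.44 and 1.26), and TNFRSF1A (-0.98 and -0.68), TNFRSF21 (-0.61 and -0.70) and FADD (-0.46 and -0.10) were lower. The probe set of RNA45SN5, a gene for the precursor of ribosomal RNA, fell by 3.02 ± 0.13 with doxorubicin (adjusted p = 2.9e-09). Its signals were 118 and 106 against 819 and 1001. With 17AAG, AUY922, E973, CDK-887 and SN38 it was at 0.77, 0.47, 0.92, -0.13 and 0.04. These values are uncertain, because the probe set may also detect near-identical copies, and which ribosomal RNA it reads was not tested.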
